A study of Caenorhabditis elegans with 4 samples.

How the data were processed

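Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done for MML-1 in wild-type Caenorhabditis elegans at the L3 larval stage. Per the labels' protocols, larvae were grown for 36 h after hatching at 20 °C, fixed for 30 min in 2% paraformaldehyde and sheared by sonication, and extract holding 2.5 mg of protein was used. The series holds 4 samples, which the labels divide into 2 ChIP samples (replicates A and B) and 2 input DNA samples (replicates A and B). The peak lists of the 2 ChIP samples were analysed here. The input samples were not analysed here as samples of their own. Per the file headers each ChIP sample was called against 1 control, and which input sample served in which call is not given in the sources used here. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only these samples, and peaks within a sample are not independent replicates.

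Alignment used Bowtie and the ce10 build, per the submitters' processing notes, and the version of Bowtie was not given in the sources used here. Peaks were called with MACS2 2.1.0.20151222, per the file headers, separately in each replicate against 1 control, with an effective genome size of 93260000 bp, a band width of 175 bp, a model fold of 5 to 50, a q threshold of 0.05 and regional backgrounds of 1000 and 10000 bp. The tag size was 75 bp and the caller kept 1 tag per position and strand, per the file headers. The fragment length modelled by the caller was 81 bp in replicate A and 72 bp in replicate B, close to or below the tag size, and it equalled the width of the narrowest peaks. The deposited pileup signal is the number of tags, taken at that length, over the summit. The deposited fold enrichment is the authors' value for each peak, a ratio of pileup plus 1 to local control background plus 1, and it was used to rank and filter peaks, to compare sets of peaks and to set the replicates side by side at shared sites. The deposited −log10 p and −log10 q values come from the same call. The score in the second deposited list of each replicate was not used, and the positions, folds, p-values and q-values of that list were identical to those used, for 653 peaks in replicate A and 744 in replicate B.

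The local control background of each peak was solved from its fold and pileup. Its lowest value, 2.34 tags in replicate A and 1.63 in replicate B, equalled the genome background. Its highest value, 28.3 and 10.9 tags, equalled the limit set by keeping 1 tag per position and strand. Peaks or sites with a local control above 2 times the genome background in their replicate (for sites, in either replicate) are called high background below. A peak was shared when it overlapped a peak of the other replicate by at least 1 bp. A site is a connected set of overlapping peaks, represented by the pair of peaks with the longest overlap. Sites with summits within 5000 bp of a neighbour form a group. Peaks on the mitochondrial genome were left out of the main results. Positions are 1-based on ce10. Chromosome lengths of ce10 came from general knowledge of that build and not from the deposited lists, and every peak ended within its chromosome.

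Sharing was tested one-sided with 10000 random rotations of 1 replicate's peaks within each chromosome, and clustering with 10000 random placements within chromosomes. Medians were compared with two-sided permutation tests and correlations with permutation p-values, each with 100000 permutations. Counts per chromosome and in the middle of the autosomes were tested with two-sided exact binomial tests. Benjamini-Hochberg adjustment ran over the 6 chromosomes, the 4 tests of shared against unshared peaks or the 3 correlations. Intervals for percentages are 95% Wilson intervals and those for ratios of counts are exact, and both cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used with fixed random seeds. On simulated peak lists of the real numbers and widths, 200 of 200 planted shared peaks were found, and the rotation test gave p under 0.05 in 4 of 100 random pairs. The clustering test did so in 5 of 100 random lists, the chromosome test in 6 of 100 and the test of centres in 2 of 100. The test of medians did so in 5 of 100 draws with no difference and in 100 of 100 with a difference of 0.5 SD. Simulated peaks, sites and values were drawn independently of each other. These rates therefore do not show how the tests behave on sites that lie in groups.

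The sites named are the 25 shared sites with the highest geometric mean of the fold in both replicates, and the 3 unshared peaks with the highest fold in each replicate. This rule, most tests and most alternatives were fixed before the data were examined. Not part of that plan were the tests of peak width, the correlations by control background, the tests of grouped against single sites and the test of the middle of X. The alternatives were another overlap rule, stricter peaks, the mitochondrial peaks, each replicate by itself, groups counted once, another width of the middle and another distance for clustering. High-background peaks left out (in either replicate, or in replicate B for the correlation), the 4 groups with the most sites left out, and the 100 peaks of highest fold were chosen after seeing the data. The gene table used with this series follows the WBcel235 assembly, and its coordinates were not combined with ce10 positions. In all, 4 planned results were not run. The promoter share, the share near noncoding genes and the 17 gene lists need gene positions on ce10. The E-box share needs the sequence under the peaks, and no genome sequence was used here. No gene is assigned to a peak here.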

Results

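MML-1 is a Myc and Mondo-like transcription factor of C. elegans that pairs with the Max-like protein MXL-2 to bind DNA. Its places on chromatin were profiled in synchronised wild-type L3 larvae by ChIP-seq in 2 replicates, A and B, each called against 1 control. The ChIP library of replicate A held 21033213 tags, of which 2694061 (12.8%) were kept at 1 tag per position and strand. That of replicate B held 30475457 tags, of which 2107570 (6.92%) were kept. The control of the replicate A call kept 15399728 tags (87.6%) and that of the replicate B call 27929584 tags (80.6%), and the file headers do not say which input sample each one was. The ChIP libraries therefore had fewer distinct tags than their controls, and replicate B rested on fewer distinct ChIP tags than replicate A.

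The first comparison asked where peaks were called and how far the replicates shared those places. Replicate A had 651 peaks on the nuclear chromosomes and replicate B had 742. Of these, 357 peaks of replicate A (54.8%, interval 51 to 58.6%) and 364 of replicate B (49.1%, 45.5 to 52.6%) overlapped a peak of the other replicate. Random rotation of the peaks gave a mean of 1.96 shared peaks in replicate A and 2.02 in replicate B, and at most 35 and 41. The one-sided p was 0.0001 for both, the smallest that 10000 rotations can give. This test shows only that the positions were not random, because background places of any ChIP can be shared as well. Peaks of high background were shared more often than other peaks. The shares were 84.4% against 49.7% in replicate A and 66.3% against 46.9% in replicate B. The shared peaks made up 338 sites, of which 305 joined 1 peak of each replicate. Their summits lay a median of 28 bp apart, and 265 sites (78.4%) had summits within 100 bp of each other. With a reciprocal overlap of 50% the shared percentages were 34.9% in replicate A and 30.6% in replicate B, and 36 of the 100 peaks of highest fold in one replicate overlapped one of the 100 of highest fold in the other. Against all peaks of the other replicate, 151 of the 163 peaks of highest fold in replicate A (92.6%) and 143 of the 186 in replicate B (76.9%) were shared.

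Peaks of low q were shared most often. With the peaks of each replicate ranked by −log10 q and divided into 4 parts of about equal size, 158 of 163 peaks in the highest part of replicate A (96.9%, interval 93.0 to 98.7%) were shared, against 41 of 163 (25.2%, 19.1 to 32.3%) in the lowest. In replicate B the values were 139 of 186 (74.7%, 68.0 to 80.4%) and 51 of 186 (27.4%, 21.5 to 34.2%). Shared peaks had a median fold enrichment of 5.39 in replicate A and 6.09 in replicate B, against 4.19 and 4.83 for unshared peaks. The difference in median log2 fold was 0.36 in replicate A and 0.33 in replicate B (permutation p = 1e-05 in each, adjusted p = 1e-05, the smallest that the permutations can give). Shared peaks were also wider, with medians of 224 bp against 117 bp in replicate A and 194.5 bp against 103 bp in replicate B (permutation p = 1e-05 in each).

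**Figure D1:**
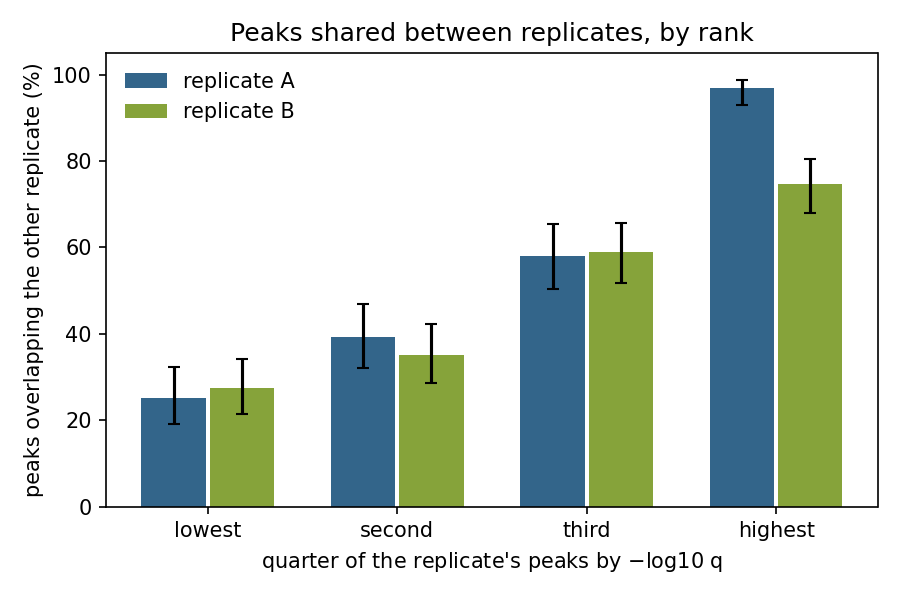
Percentage of peaks that overlap a peak of the other replicate (y axis), for the peaks of each replicate divided into 4 parts by −log10 q (x axis), with 95% Wilson intervals as error bars. The share was 96.9% in the highest part of replicate A and 74.7% in that of replicate B.

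The site with the highest mean fold lay on chromosome X at 6748884 to 6750624, with a fold of 18.2 in replicate A and 17.5 in replicate B. The next was on chromosome II at 13461676 to 13462548, with 19.2 and 14.5. A site on chromosome I at 7661918 to 7662512 had folds of 16.7 and 16.6. Chromosome X held the next one, at 6742809 to 6744438, with 16.5 and 13.5. On chromosome V, the site at 19529137 to 19529624 had 16.24 and 11.15. On chromosome IV, that at 6878912 to 6879274 had 16.27 and 10.99. A second region of X, at 13353283 to 13353976, had 16.8 and 10.7. A second site of chromosome II, at 13469061 to 13469847, had 11.06 and 15.99. Near the left end of chromosome I, the site at 315092 to 315423 had 14.96 and 11.8. Chromosome I also held the tenth site of the list, at 6498415 to 6500032, with 11.7 and 13.2. The local control at these 10 sites was at most 1.42 times the genome background in replicate A.

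The 25 sites of highest mean fold ranged from 10.0 to 17.9 in that mean. Of these, 10 lay on chromosome X, 5 on I, 3 each on II and IV, and 2 each on III and V. Several of the 10 on X belonged to the same group, so they are not 10 separate regions, and their number was not tested. In 19 of the 25, another shared site lay within 5000 bp. A high control background was found at 3 of them, on X at 15810987 to 15811087, on III at 10224985 to 10225403 and on I at 933485 to 933699. These 3 had folds of 7.807, 7.667 and 6.999 in replicate A and of 18.5, 15.1 and 15.3 in replicate B. Among unshared peaks, the highest folds in replicate A were 6.89 on V at 14831587 to 14831790, 6.89 on III at 11026623 to 11026894 and 6.70 on V at 12637802 to 12638048. In replicate B they were 11.7 on IV at 9048541 to 9048669, 11.4 on III at 5356790 to 5356880 and 11.4 on I at 10947514 to 10947610.

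The second comparison set the fold of each shared site in replicate A against that in replicate B. At the 263 sites without a high control background, the folds rose together across sites (Pearson r = 0.65, Spearman rho = 0.58), with medians of 5.87 in replicate A and 5.78 in replicate B. At the 75 sites with a high control background, r was 0.54 and rho 0.49, and the fold was higher in replicate B at 75 of 75 sites, with medians of 4.32 and 9.21. This division uses the local control, which enters the fold itself, and a high control in replicate A lowers its fold. With the background judged from replicate B alone, which works the other way, the fold was higher in replicate B at 55 of 55 sites (medians 4.32 and 9.21), and rho was 0.46 at the other 283. Over all 338 sites r was 0.35 and rho 0.30. The permutation p was at most 2e-05 for each of the 3 sets, adjusted p included. Sites are not independent replicates. Among the upper 50% of each replicate's peaks by −log10 q (326 and 372 peaks), which left 198 sites, rho was 0.050 and did not pass the test (permutation p = 0.487). Sites of high background were kept in that set, and rho without them was not computed there.

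**Figure D2:**
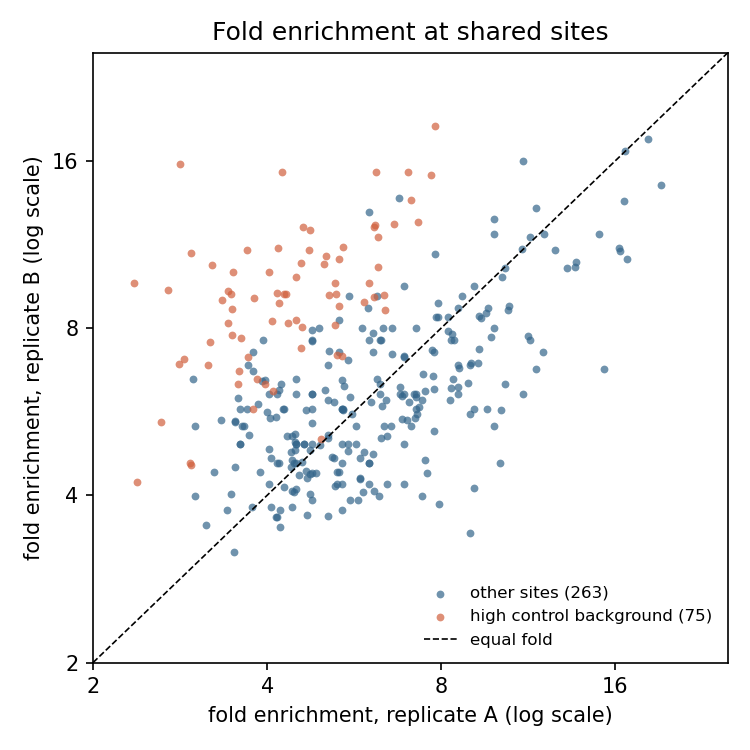
Fold enrichment of each shared site in replicate A (x axis) and replicate B (y axis), both on log scales, with the dashed line at equal folds. The 75 sites with a high control background lie above the line, and the other 263 lie on both sides of it.

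The third comparison asked how shared sites were spread over the chromosomes. Chromosome X held 78 sites, 1.31 times the number its length gives (exact interval 1.06 to 1.58). The autosomes had ratios of 1.00 on I, 0.91 on II, 0.75 on III, 1.00 on IV and 0.96 on V. No chromosome passed the exact binomial test after adjustment (X, p = 0.0123, adjusted p = 0.074, and III, p = 0.0816, adjusted p = 0.245). All peaks of replicate A gave a ratio of 1.22 on X (exact binomial adjusted p = 0.0706) and those of replicate B gave 1.21 (adjusted p = 0.0645). The X result depended on the setting. It passed the exact binomial test with a reciprocal overlap of 50% (1.42, adjusted p = 0.0309), and in the upper 50% by q (1.46, adjusted p = 0.0296), and it was 1.21 (adjusted p = 0.723) with each group of sites counted once. With the mitochondrial peaks kept, its adjusted p was 0.0446 at an unadjusted exact binomial p of 0.0127, because the mitochondrial genome, with a lower p, took the first rank in the adjustment.

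The middle of the autosomes, where genes lie more densely than on the arms, held more shared sites than its length gives. Of 260 autosomal sites, 116 (44.6%, interval 38.7 to 50.7%) lay in the middle 33.3% of their chromosome (exact binomial p = 0.000167). The percentage was 60% on III (21 of 35 sites) and 54.9% on I (28 of 51 sites), each with an adjusted p of 0.0053. It was 42.4% on IV, 38.2% on V and 34% on II, which did not pass the exact binomial test (adjusted p = 0.333, 0.528 and 1). On X it was 39.7% (exact binomial, adjusted p = 0.347). Each replicate by itself gave 45.6% (A) and 45.2% (B) over the autosomes. These tests treat sites as independent, although many lie in groups. With each group counted once the call on I was lost (48.5%, 16 of 33, exact binomial adjusted p = 0.283) and that on III was not (62.5%, 15 of 24, adjusted p = 0.024). The upper 50% of peaks by q ended both calls (exact binomial adjusted p = 0.126 for each), a reciprocal overlap of 50% ended that on I (adjusted p = 0.43) and a fold of at least 4 ended that on III (adjusted p = 0.0678).

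**Figure D3:**
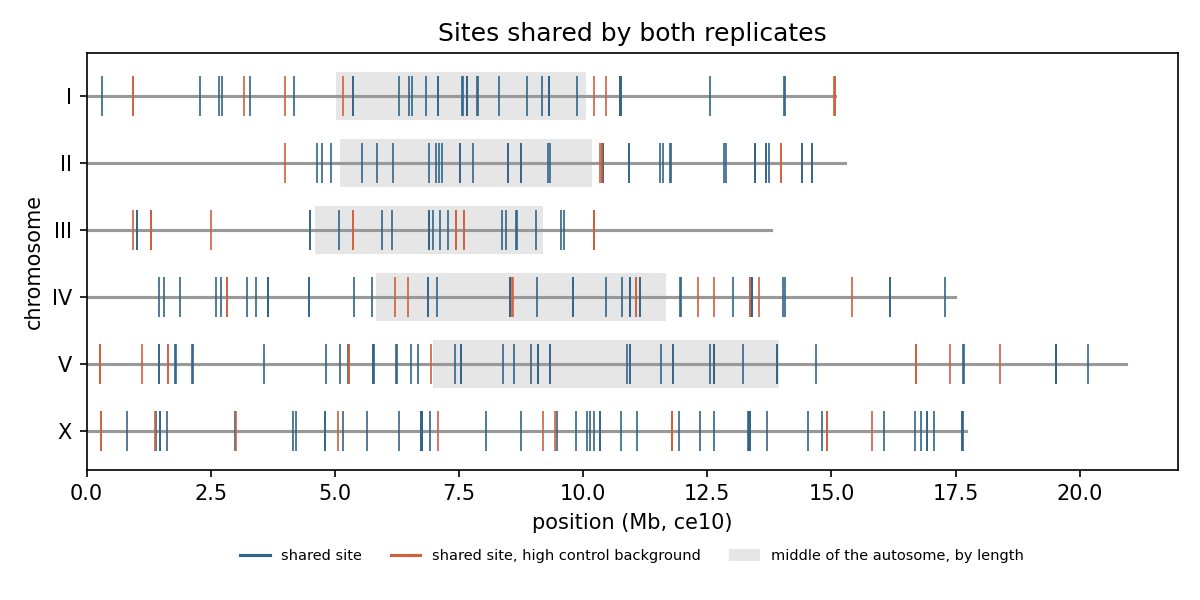
Position in Mb on ce10 (x axis) of the 338 shared sites on each nuclear chromosome (y axis), with sites of high control background in orange and the middle 33.3% of each autosome in grey. The middle held 116 of 260 autosomal sites.

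Shared sites lay in groups. Another shared site was found within 5000 bp of 180 of the 338 sites (53.3%), against a mean of 3.33% and at most 9.17% in random placements (permutation p = 0.0001, the smallest that 10000 placements can give). The same measure was 53.9% for all peaks of replicate A and 66.4% for those of replicate B. In all, 62 groups had at least 2 sites and 21 had at least 3, and these 21 held 98 sites.

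The group with the most sites lay on chromosome X at 6735541 to 6750624, with 10 sites over 15.1 kb and a median fold of 9.24 in replicate A and 7.99 in replicate B. Its local control was 1.00 times the genome background in both. A second group on X, at 13348345 to 13360847, had 9 sites with median folds of 6.89 and 6.26. Groups of 6 sites lay on IV at 8525876 to 8535280 (median folds 8.05 and 6.28) and on I at 7656720 to 7663912 (5.22 and 6.48). Among the groups of 5, those on V at 16707365 to 16709411 and on X at 11785705 to 11789450 had a local control of 3.66 and 5.01 times the genome background in replicate A. Grouped sites had a median mean fold of 6.31 and single sites 5.47 (permutation p = 0.00108). Without high-background sites the medians were 6.31 for 133 grouped sites and 5.27 for 130 single sites (permutation p = 0.00092). Both tests treat sites as independent, although those of a group lie close together, and no test by group was run.

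**Figure D4:**
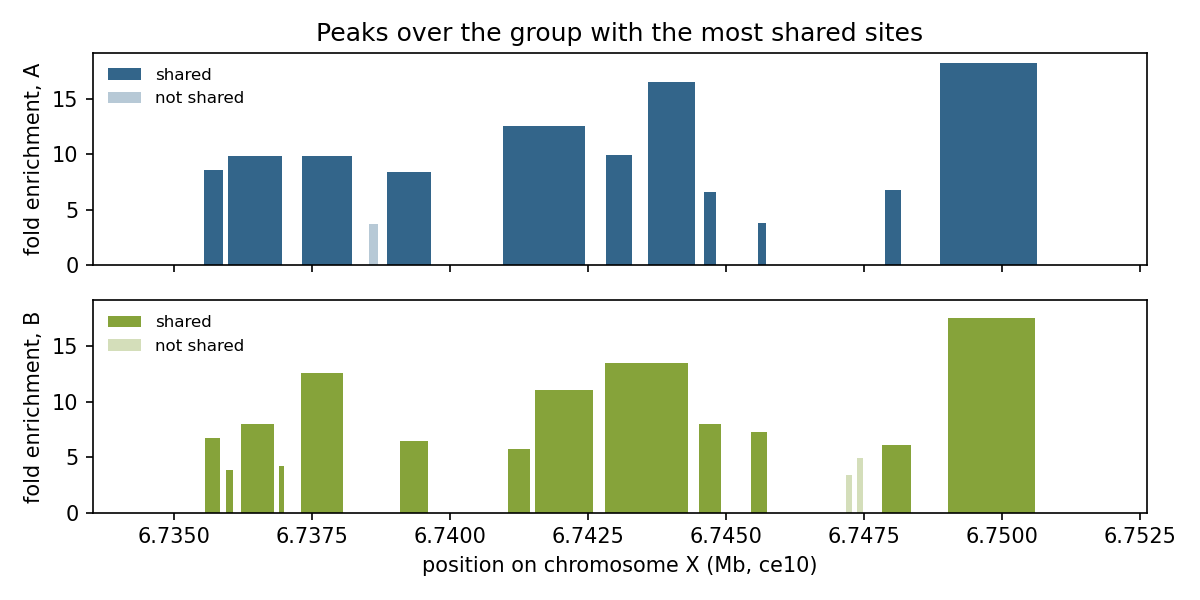
Peaks of replicate A (upper panel) and replicate B (lower panel) over the group of 10 shared sites on chromosome X, with position in Mb on ce10 (x axis) and fold enrichment (y axis), each bar as wide as its peak and pale where the peak was not shared. The bar with the highest fold, at the right, reaches 18.2 in replicate A and 17.5 in replicate B.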

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

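The tests below were chosen after the results were seen, except that of peaks of replicate A within 500 bp.

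The mitochondrial genome lay outside the comparisons and had peaks in both replicates above the control. In replicate A the peak at 26 to 13347 had a fold of 4.42 and that at 13563 to 13662 a fold of 4.99. In replicate B the peak at 19 to 13453 had 9.02 and that at 13555 to 13733 had 12.2.

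Peaks over the mitochondrial genome and the right end of chromosome I, where the ribosomal RNA genes lie, were weighed together with sites of high control background. Not all of the 11 peaks there had a control at the limit of 1 tag per position and strand. The 4 peaks up to 200 bp wide had a local control of 41.7 to 47.2% of that limit. The 7 wider peaks lay at 97.1% of the limit or above, so a control held down by the limit may act at the wide ones. The lowest value alone gives no verdict on the 11 peaks as a set. The 55 sites with a high background in replicate B were compared with the other 283 sites, a choice that works against a lower control there. The control made up 65.5% of the shift in the log2 ratio of replicate B to A, and the ChIP pileup 34.5%. At the 55 sites themselves the mean log2 ratio was 1.02, with 1.08 from the control and -0.056 from the pileup. At the 263 sites without a high background in either replicate, which are among the other 283, the pileup part was -0.43. The pileup part of the shift is therefore relative to the other 283 sites, and its source stays open. Evenly spread control tags under the same limit would give only 28.7% of the observed drop of the control from replicate A to B, so unevenly spread tags or another difference between the controls stay open, and no biological explanation was tested.

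Of the 186 peaks of replicate B in the highest of 4 parts by −log10 q, 47 (25.3%, interval 19.6 to 32.0%) were not shared. How near the signal of replicate A came to its own threshold there was not analysed here, so loss near that threshold stays open. A peak of replicate A lay within 500 bp of 17% of these 47 (interval 8.89 to 30.1%), which argues against a mere shift to the side, although the interval leaves some room. Their median width was 110 bp, against 275 bp for shared peaks of the same part (permutation p = 0.00074), which narrow stacks of tags could give. Unshared peaks of replicate B had a median of 103 bp in all, so the narrow width extends to unshared peaks in general. In replicate B, 57.9% of unshared and 26.1% of shared peaks were narrower than 112.5 bp. Another peak of replicate B lay within 5000 bp of 40 of the 47 (85.1%), against 66.4% of all peaks of replicate B. A high background was found at 13 of the 47, against 83 of all 742 peaks of replicate B (11.2%). Both comparisons are with all peaks of replicate B, weaker ones included. Neither share was computed for the shared peaks of the same part, so these values do not set the 47 apart from other strong peaks. No biological explanation was tested.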

How the results depend on the processing

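Of 179 values under alternatives, 144 kept their direction and their side of the threshold or, for counts of sites, stayed within 1.5 times. No paired analysis was possible because no test here sets the ChIP group against the input group, and all tests are within or between the 2 ChIP replicates. The promoter, noncoding gene, E-box and gene list results and their alternatives were not run. Leaving out high-background peaks, leaving out the 4 groups with the most sites, and taking the 100 peaks of highest fold were chosen after seeing the data. Sharing passed its test under every alternative run, at 34.9 to 63.8% of replicate A and 30.6 to 55.4% of replicate B. So did the middle of the autosomes as a whole, at 1.24 to 1.52 times the even share, and clustering, at 44.9 to 66.4%, the latter for all peaks of replicate B. The higher fold of shared peaks passed as well, at 0.24 to 0.46 (log2) in replicate A and 0.22 to 0.49 in replicate B. The upper 50% by q left 198 sites, as it holds fewer peaks, and a rho of 0.050 with high-background sites kept. The X ratio passed its test at 1.42 with 50% reciprocal overlap, 1.46 in the upper 50% by q and 1.298 with mitochondrial peaks, there only because the mitochondrial genome took the first rank in the adjustment. The autosomes did not pass under any setting, and ratios near 1 changed side. With 50% overlap I was 0.97 and IV 0.96. In the upper 50% by q I was 0.91 and IV 0.98. With fold of at least 4, IV was 0.91. With mitochondrial peaks I was 0.998 and IV 0.995. Without high-background peaks II was 1.05 and IV 0.98. With groups counted once I was 0.998. Without the 4 groups, 2 of which lie on X, X was 1.09 (exact binomial adjusted p = 1), I 0.975, II 1.00, IV 0.99 and V 1.06. With either replicate left out I ranged from 0.96 to 1.02, II from 0.86 to 1.14 and IV from 0.89 to 1.04. For the middle of single chromosomes, I did not pass at 1.36 with 50% overlap, 1.67 in the upper 50% by q and 1.45 with groups counted once, and III at 1.64 in the upper 50% and 1.67 with fold of at least 4. Others changed side or passed, at 0.95 on V with 50% overlap, 0.71 on II with summits within 100 bp, 1.00 on II and 0.97 on V in the upper 50%, 1.5 on V without high-background peaks and 1.00 on X in a wider middle. With either replicate left out IV ranged from 1.12 to 1.36 and X from 1.11 to 1.253, and both passed without replicate A (exact binomial adjusted p = 0.0195 and 0.042). The cause of these changes was not tested, though some settings leave fewer sites. Few distinct ChIP tags limit what weak peaks can show.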

Other observations

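The groups of peaks seen in 1 replicate were looked at after the other results, and the tests of the control background at grouped sites and of the distance between their edges were chosen after that result was seen.

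Some stretches between shared sites or away from them held several peaks of replicate B that replicate A did not share. In replicate B, 8 regions had at least 5 unshared peaks within 5000 bp of each other, 51 peaks in all, whereas replicate A had 0 such regions. Peaks were chosen here for not overlapping replicate A, which had 0 peaks in 6 of the 8 regions and 1 peak in each of the other 2. On chromosome I, 8 unshared peaks lay at 10945999 to 10952978 with a median fold of 7.04, and 0 peaks of replicate A lay within 5000 bp of the region. On chromosome II, 8 lay at 10926587 to 10930760 with a median fold of 4.00 and 2 peaks of replicate A within 5000 bp. On chromosome III, 7 lay at 10904241 to 10909836 with a median fold of 5.93, with 0 peaks of replicate A within 5000 bp. On IV, 7 lay at 8573856 to 8580078 with a median fold of 5.33, where 2 peaks of replicate A lay within 5000 bp. The median peak width was 577 bp in the region on III and 73 to 150 bp in the other regions, against a tag size of 75 bp. The median local control was at most 1.05 times the genome background over these 4 regions and 1.13 to 1.99 times over the other 4. Another unshared peak lay within 5000 bp of 50.5% of the unshared peaks of replicate B and 25.2% of those of replicate A, against means of 3.74% and 2.88% in random placements (permutation p = 0.0001 in each, the smallest that the placements can give). The difference between the replicates was not tested.

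Shared sites that lie in groups within 5000 bp were weighed against technical explanations. The median local control at the 180 grouped sites was 1.196 times the genome background in replicate A and 1.09 in replicate B. This argues against repeats or extra copies at the typical grouped site only. A high background was found at 47 of the 180 grouped sites, against 75 of all 338 shared sites (22.2%). Repeats or extra copies stay open for those 47, and grouped sites were not tested against single sites in this respect. The edges of neighbouring sites within groups lay a median of 693 bp apart (bootstrap interval 551 to 1066 bp, 118 distances). These distances were taken between shared sites only, although unshared peaks lay between some of them. They therefore cannot decide whether broad regions were divided by the caller. Of the 118 distances, 19 were under 200 bp, and the smallest, in the group of 10 sites on X, was 42 bp. No biological explanation was tested.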
